A study of Rattus norvegicus with 16 samples.

How the data were processed

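Primary rat aortic smooth muscle cells had been cultured in medium with 20% serum. For 48 h they carried an adenovirus, either a control virus or a virus with a short hairpin RNA against Nat10. Input RNA was sequenced from 3 control and 3 knockdown libraries. RNA fragments of 100 to 200 nt from the same number of libraries were immunoprecipitated with an antibody against N4-acetylcytidine (ac4C), the cytidine modification that the NAT10 enzyme places on RNA. In a separate assay, RNA bound to the NAT10 protein was immunoprecipitated from 3 libraries (NAT10 RIP). The non-immunoprecipitated library of that assay was not analysed here. Groups and replicate numbers came from the sample titles. The series design calls the replicates biological repeats but does not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical.

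The authors deposited expression as FPKM, fragments per kilobase of gene scaled for library size, for 32883 Ensembl genes in the 6 input libraries. Of these genes, 11482 were listed at 0 in every library. The submitters' processing notes name cutadapt 2.5, HISAT2 2.1.0, featureCounts 1.6.3, HOMER 4.10.4 and DESeq2, and the genome builds rn6, GRCm38 and GRCh38, without saying which step used which. For the ac4C libraries the authors deposited 1 peak list each, with a p-value per peak and no enrichment; whether it is a raw or an adjusted p is not given in the sources used here. For the NAT10 RIP libraries the authors deposited 1 peak list each, with a log2 enrichment and a p-value per peak, per the file headers. The peak callers and the control used for the RIP enrichment are not given in the sources used here. Peak scores are the authors' own and were used to describe, rank or filter peaks within a list. To rank genes with ac4C peaks in 1 group only, the best -log10 p per library was also averaged over the 3 lists of the group, whose scales differ. Coordinates follow the deposited lists, with 1 added to each start so that positions count from 1, and were not moved to another build.

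The FPKM values still held the fragment numbers behind them. For each gene, a search over lengths from 20 to 130000 nt found whole fragments in all 6 libraries for 21401 of the 21401 genes above 0 (relative tolerance 2e-08, absolute tolerance 1e-06), and for 0 of 500 genes whose decimals had been altered. The recovered fragments numbered 12065991, 8171176 and 8623541 in control libraries 1 to 3 and 6417941, 7106004 and 7468528 in knockdown libraries 1 to 3. The search used the authors' divisor of each library. It was worked out from genes with 1 row in ac4C control list 1, at the p-value that most rows there share. The length of that row was taken as the gene's length, and 945 to 1204 genes per library gave the same divisor. The authors' divisor per library was proportional to its median-of-ratios size factor and not to its total, so the deposited values were already scaled between libraries. Because the unit is FPKM, the main test stayed on the log scale, and the recovered fragments entered only a voom fit added later.

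Genes with a mean FPKM of at least 1 over the 6 libraries (13450 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a mean-variance trend, group as the only term, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Log2 changes are on that scale, which understates the change of low genes. Of 23 gene lists, the 20 with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 20 lists. Camera with an estimated correlation and fry were run beside it. The lists covered contractile smooth muscle, collagens and matrix, integrins and focal adhesion, cell cycle, p53 targets, ribosome biogenesis, cytosolic ribosomal proteins, interferon response, inflammatory cytokines and NF-kB, unfolded protein and amino acid stress, glycolysis and hypoxia, cholesterol synthesis, the mitochondrial respiratory chain, growth factors and receptors of smooth muscle, matrix proteases and migration, osteochondrogenic genes, immediate early and heat shock genes, RNA acetylation and modification enzymes, and markers of endothelial cells, leukocytes, adventitial fibroblasts, Schwann and neural cells, and adipocytes and mesothelium. Symbols were matched to the deposited names, and 7 were found through another name in the RefSeq table of assembly GRCr8.

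The lists, the tests, the first set of other fits and filters, and the rule for naming genes were fixed before the data were examined. The rule named Nat10, Itgb1 and Col1a2; the 8 genes with the largest rise and fall among those past the threshold or, where fewer pass, those with the smallest p, given as not passing; 3 members of each called list; the 6 highest-scoring genes with ac4C peaks in 1 group only, in each direction; and the 6 NAT10-bound genes with the highest enrichment. Rfam family names, which several genes share, and genes with overlapping groups were left out of the second part when it was filled with genes that did not pass, a choice made after their values were seen. A part of the rule for genes that fell and held both kinds of peak named none. Some genes that the rule names are not reported here.

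A gene counted as an ac4C gene when all 3 control libraries listed a peak in it, and as NAT10-bound when all 3 RIP libraries did. Numbers of peaks were compared with a two-sided exact permutation test on their log2 values, which for 3 against 3 libraries cannot give a p under 0.1. Overlaps were tested with two-sided Fisher's exact tests over the 13450 tested genes, and against 10000 random sets matched on deciles of mean expression and, in an addition, also on 5 classes of gene length. Overlap of peaks was also counted with at least 1 shared base and with 50% of both peaks. The recovered lengths served for the length matching.

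Other fits and filters chosen beforehand were a pseudocount of 0.1, other expression filters, quantile and median-of-ratios scaling, the replicate number as a block, limma without the trend, a 1.5-fold threshold, the better-scoring part of each peak list, equal numbers of peaks, peaks in at least 2 libraries, and leaving out each library in turn. Added after the data were seen were voom, library quality weights, scaling to the total, an average of control libraries 2 and 3, leaving out control library 1 and knockdown library 2 together, removal of peaks that share 1 p-value within a list, and the length matching. The fit was tested on simulated data for 13450 genes, 200 of them changed. With the spread of all 6 libraries it recovered 15% of the 2-fold and 86% of the 4-fold changes and called 9 unchanged genes. With the smaller spread of the control libraries it recovered 58% and 93% and called 7. Every simulated gene had the same dispersion, 0.0410 for all 6 libraries or 0.0105 for the controls. The simulated libraries held no structure besides group and depth, so these shares may not hold for the real ones. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.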

Results

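The series asked what NAT10, the enzyme that acetylates cytidines in RNA to ac4C, does in vascular smooth muscle cells, the contractile cells of the artery wall that also make its matrix. Primary cells from rat aorta were given an adenovirus with a short hairpin RNA against Nat10 or a control adenovirus for 48 h. Gene expression was measured in 3 control and 3 knockdown libraries with 6417941 to 12065991 recovered fragments each. The ac4C peak lists came from 3 control and 3 knockdown libraries and the NAT10-bound RNA from 3 further libraries. The read depth of the immunoprecipitated libraries was unknown, since peak lists hold no read totals.

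The target of the hairpin stood lower in every knockdown library than in any control, but did not pass the threshold over all genes. Nat10 (ENSRNOG00000008663) stood at 7.69, 9.22 and 9.95 FPKM in the controls and at 4.38, 3.68 and 4.58 FPKM in the knockdown libraries. The means were 8.96 ± 1.15 and 4.21 ± 0.470 FPKM (SD, n = 3 each). The log2 change was -0.93 (SE 0.19), with an unadjusted p of 0.00159 and an adjusted p of 0.227 in limma. With library quality weights the adjusted p was 0.0399, against 0.108 to 0.797 in the other 17 alternatives.

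Single genes stayed below the threshold, but many of those that differed most were parts of the cytoskeleton and matrix. Col4a2, a chain of basement membrane collagen, stood at 119 ± 35.0 FPKM in controls and 16.8 ± 3.85 FPKM in knockdown cells (SD, n = 3 each). Actr2, a subunit of the actin-nucleating Arp2/3 complex, stood at 112 ± 12.6 and 36.6 ± 7.64 FPKM. Nexn, an actin-binding protein of muscle, stood at 43.2 ± 6.90 and 14.5 ± 2.30 FPKM, and Gnai2, an inhibitory G protein subunit, at 271 ± 19.4 and 74.1 ± 19.8 FPKM. In the other direction, Ednrb, the endothelin B receptor, stood at 2.01 ± 0.195 and 7.32 ± 1.41 FPKM.

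By limma, 0 genes were higher and 0 lower after knockdown, with a lowest adjusted p of 0.155. At an unadjusted p under 0.05, 744 genes were higher and 935 lower. Voom also called 0 genes, and library quality weights called 120 higher and 215 lower. These weights were 0.559, 3.80 and 3.57 for control libraries 1 to 3 and 1.35, 0.235 and 0.416 for knockdown libraries 1 to 3. The weighted calls thus lean on control libraries 2 and 3, the most alike pair, which may not be separate cultures. The libraries did not overlap between the groups for 1295 higher and 1471 lower genes, 20.6% of those tested. The 10% given by chance is an average over all splits of the libraries. Genes move together, so 1 split can exceed it without an effect of the groups. Control library 1 and knockdown libraries 1 and 2 against the rest gave 1755 genes at an unadjusted p under 0.05 in limma, against 1679 in the real split. Scaling to the total moved the median log2 change of all genes from -0.01 to 0.12 and turned the split at an unadjusted p under 0.05 to 1124 higher and 569 lower. Other lower genes named by the rule were Eid1 (48.5 to 10.1 FPKM), Mlf2 (82.3 to 32.0 FPKM) and Crip2 (68.2 to 27.1 FPKM). Higher ones were Alg10 (9.87 to 21.6 FPKM), Mfap3l (6.19 to 12.8 FPKM), Hvcn1, a proton channel (8.26 to 16.8 FPKM), Rbm15, an adaptor of the m6A methyltransferase (15.1 to 28.5 FPKM), and the p53 target Zmat3 (31.6 to 60.9 FPKM). Mir449a was listed at 0 in all 3 controls and at a mean of 3.38 ± 1.56 FPKM in knockdown cells, which rests on 3, 3 and 1 recovered fragments. Itgb1, the beta-1 integrin chain, stood at 644 ± 94.1 FPKM in controls and at 160, 87.4 and 323.9 FPKM in the knockdown libraries (log2 -1.94, SE 0.45, limma adjusted p = 0.266). Col1a2, a chain of type I collagen, stood at 192 ± 23.99 and 101 ± 69.5 FPKM with overlapping groups (limma adjusted p = 0.389).

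**Figure D1:**
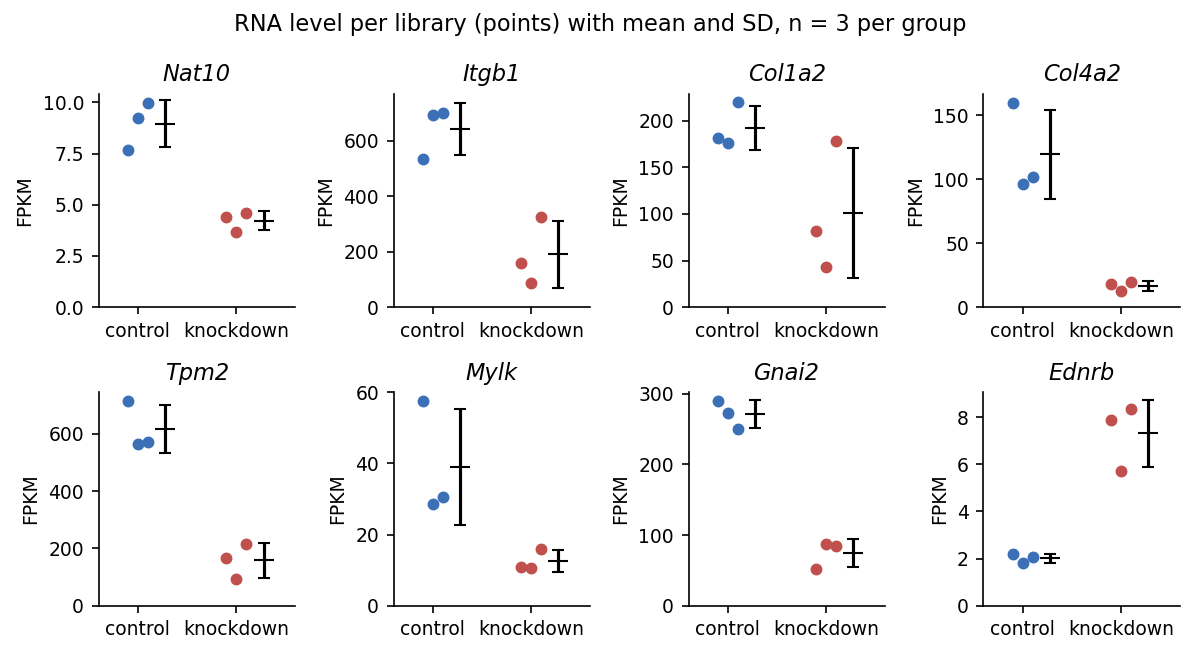
RNA level in FPKM (linear axes from 0) of 8 genes in each control (blue) and Nat10 knockdown (red) library, with the mean and SD of 3 libraries per group. Nat10 stood at 7.69 to 9.95 FPKM in controls and 3.68 to 4.58 FPKM in knockdown libraries, and of the 8 genes Col1a2 alone had overlapping groups.

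Genes of the contractile apparatus stood lower after Nat10 knockdown, as did genes of the matrix, of cell adhesion and of adventitial fibroblasts. Camera called these lists at its preset correlation and none with an estimated one (adjusted p = 0.709 for contractile and fibroblast genes, adjusted p = 0.906 for matrix and adhesion genes), and the adhesion call was also lost without single libraries. All 18 measured contractile genes had a negative log2 change, with a median of -1.26. Tpm2, a tropomyosin of the thin filament, stood at 618 ± 84.7 FPKM in controls and 158 ± 61.3 FPKM after knockdown (SD, n = 3 each). Mylk, the kinase that starts smooth muscle contraction, stood at 39.0 ± 16.2 and 12.5 ± 3.03 FPKM, and Lmod1, an actin filament nucleator, at 33.3 ± 6.17 and 9.79 ± 4.99 FPKM. By camera the contractile list moved down (adjusted p = 2.03e-11 by camera, adjusted p = 0.709 with an estimated correlation). An unadjusted p under 0.05 was reached by 15 of the 18, 14 passed when adjusted over the list alone, and 0 passed over all genes. Without control library 1 and knockdown library 2 together the median was -0.79.

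Of 33 measured collagen and matrix genes, 31 had a negative change, with a median of -0.83. Plod2, which hydroxylates lysines of collagen, stood at 392 ± 19.2 FPKM in controls and 104 ± 54.1 FPKM after knockdown. Col5a2, a fibrillar collagen chain, stood at 944 ± 97.4 and 167 ± 125 FPKM, beside Col4a2 above. The list moved down by camera (adjusted p = 1.83e-09, adjusted p = 0.906 with an estimated correlation). Adjusted over the list alone 7 genes passed, and 0 over all genes. Knockdown library 3 stood closest to the controls, with a median deviation of -0.10 against -0.86 and -1.13 in knockdown libraries 1 and 2. The median was -0.51 without knockdown library 1 and -0.48 without knockdown library 2.

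Integrin and focal adhesion genes had a median of -0.43, with 18 of 25 negative. Beside Itgb1, Tln1, which links integrins to actin, stood at 147 ± 4.72 and 93.2 ± 15.0 FPKM, and the actin crosslinker Actn1 at 538 ± 81.7 and 275 ± 101 FPKM. Adventitial fibroblast markers had a median of -0.55, with 10 of 12 negative. Col14a1 stood at 38.7 ± 1.64 and 15.8 ± 6.55 FPKM, Scara5 at 21.0 ± 3.79 and 9.25 ± 4.27 FPKM, and Pdgfra at 27.5 ± 1.19 and 18.2 ± 5.80 FPKM. Both lists moved down by camera (adjusted p = 0.00677 each), with an adjusted p of 0.906 for integrins and 0.709 for fibroblast markers with an estimated correlation. Adjusted over the list alone, 0 integrin genes and 2 fibroblast markers passed. Camera's adjusted p for integrins was 0.0602 without control library 1, 0.0978 without knockdown library 2 and 0.356 without both, in a range of 0.000207 to 0.356 over 18 alternatives. The integrin median was -0.23 without knockdown library 2, -0.20 without both and -0.27 with scaling to the total, and the fibroblast median was -0.33 without knockdown library 2.

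Genes of cholesterol synthesis, ribosome biogenesis and the cell cycle stood slightly higher, in calls that camera made at its preset correlation and lost with an estimated one (adjusted p = 0.906 each) or without single libraries. Of 21 cholesterol synthesis genes, 18 had a positive change, with a median of 0.37. Sc5d, a desaturase of the pathway's last steps, stood at 11.8 ± 1.98 FPKM in controls and 20.5 ± 2.63 FPKM after knockdown. Hsd17b7, another enzyme of the pathway, stood at 1.13 ± 0.311 and 2.35 ± 0.310 FPKM. Of 32 ribosome biogenesis genes, 26 were positive with a median of 0.24. The processing factors Nop14, Utp15 and Rrp12 stood at 19.0 ± 1.24, 13.5 ± 1.72 and 7.62 ± 1.21 FPKM in controls and at 25.9 ± 1.24, 20.4 ± 3.52 and 14.3 ± 6.05 FPKM after knockdown. Of 37 cell cycle genes, 28 were positive with a median of 0.17. The replication licensing factors Cdt1 and Mcm4 and the mitotic checkpoint kinase Bub1b stood at 5.57 ± 2.07, 13.8 ± 3.75 and 3.31 ± 0.918 FPKM in controls and at 12.7 ± 4.71, 25.5 ± 11.4 and 7.33 ± 4.28 FPKM after knockdown.

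Camera gave these lists adjusted p-values of 0.00235, 0.00677 and 0.0415, and 0 members of any of them passed when adjusted over the list alone. All of these calls rested on single libraries. The cholesterol list had a median of 0.12 and an adjusted p of 0.0931 without knockdown library 2, a median of 0.08 without that library and control library 1 (adjusted p = 0.347) and 0.63 without knockdown library 3 (range of adjusted p 2.4e-05 to 0.347 over 18 alternatives). Ribosome biogenesis had an adjusted p of 0.128 without control library 1 (median 0.14), 0.247 without knockdown library 1 (0.15) and 0.249 without knockdown library 3 (0.12), in a range of 3.55e-09 to 0.249. Its median was 0.48 without knockdown library 2, 0.43 without that library and control library 1, and 0.37 with scaling to the total. The cell cycle median was 8.87e-05 without control library 1 (adjusted p = 0.878) and -0.11 without knockdown library 1 (adjusted p = 0.551), and its lowest adjusted p over the alternatives was 0.000207, with a median of 0.42, without knockdown library 3. The cell cycle adjusted p was 0.0938 with scaling to the total (median 0.31), 0.136 over all genes above 0 and 0.356 without control library 1 and knockdown library 2 together (median 0.09). Its median was 0.30 without control library 2, 0.34 without control library 3, 0.30 with library quality weights and 0.31 with control libraries 2 and 3 averaged.

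**Figure D2:**
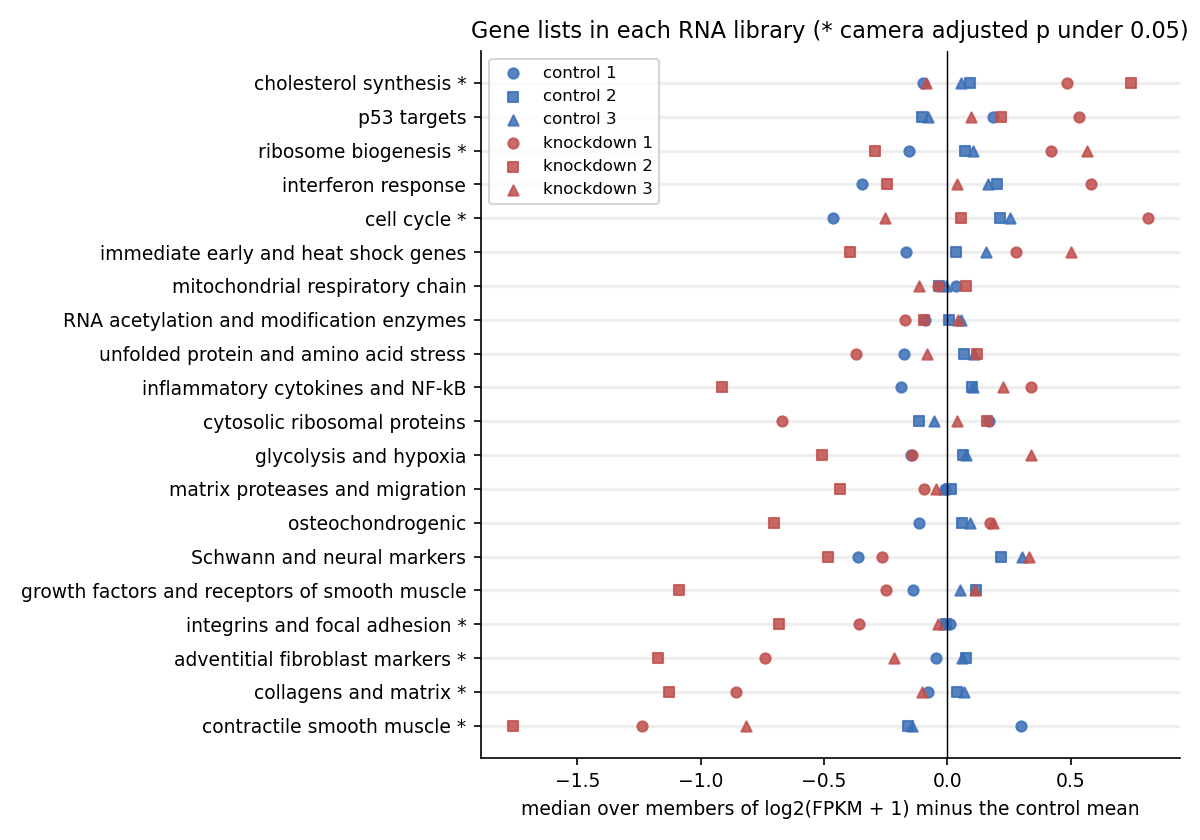
Median over the members of each of 20 gene lists of the difference from the control mean in log2(FPKM + 1), for each control (blue) and knockdown (red) library. The contractile list lay below every control in all 3 knockdown libraries, and the 7 starred lists had a camera adjusted p under 0.05 (all at least 0.709 with an estimated correlation).

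The other 13 tested lists did not pass. The p53 targets had a median of 0.30 with members in both directions (camera adjusted p = 0.0534). Zmat3, Aen (40.3 to 69.0 FPKM), Eda2r (10.39 to 19.7 FPKM) and Tp53inp1 (31.8 to 94.8 FPKM) were on the higher side, and Ccng1 (66.5 to 34.6 FPKM) and Fas (18.4 to 10.9 FPKM) on the lower. Adjusted over the list alone, 3 p53 targets were higher and 2 lower. Over 18 alternatives the adjusted p of p53 targets ran from 0.00639 to 0.292, and it was under 0.05 without control library 1 (0.0394), without knockdown library 3 (0.0126), without control library 1 and knockdown library 2 together (0.0381), with the replicate block (0.0339), quantile normalization (0.0472), voom (0.0484) and quality weights (0.00639). Cytosolic ribosomal protein genes had a median of -0.18, with 41 of 43 negative (camera adjusted p = 0.0534). Their median was 0.09, with a test pointing up, without knockdown library 1 (adjusted p = 0.375) and -0.08 without control library 1 (0.443). The adjusted p was under 0.05 without control library 2 (0.0150), control library 3 (0.0466), knockdown library 2 (0.000292) or knockdown library 3 (0.0170) and in 5 other alternatives, in a range of 7.47e-05 with quality weights to 0.453.

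Growth factors and receptors of smooth muscle had a median of -0.25 (adjusted p = 0.0677). It was -0.51 without knockdown library 3 (adjusted p = 0.00202) and -0.04 with a test pointing up without knockdown library 2 (0.966), the ends of its range, and 4 other alternatives passed. Lists farther from passing were glycolysis and hypoxia with a median of -0.18 (adjusted p = 0.643), matrix proteases and migration -0.19 (adjusted p = 0.478) and osteochondrogenic genes -0.21 (adjusted p = 0.558). The median was 0.20 for interferon response (adjusted p = 0.418) and lay closer to 0 for immediate early and heat shock genes (0.11, adjusted p = 0.558), inflammatory cytokines and NF-kB (-0.05, adjusted p = 0.643), unfolded protein and amino acid stress (-0.03, adjusted p = 0.558), the respiratory chain (-0.03, adjusted p = 0.643) and RNA acetylation and modification enzymes (-0.03, adjusted p = 0.913). The Schwann and neural list had a median of -0.21 but a mean of 0.06 and a camera test pointing up (adjusted p = 0.781). Immediate early and heat shock genes passed without knockdown library 2 (median 0.53, adjusted p = 0.0103, in a range up to 0.888), where inflammatory genes had a median of 0.52 (adjusted p = 0.0803), glycolysis 0.14 (0.310) and osteochondrogenic genes 0.24 (0.966). The unfolded protein and amino acid stress list passed with quality weights (median -0.30, adjusted p = 0.0307) and without control library 1 and knockdown library 2 together (-0.36, adjusted p = 0.0167, in a range up to 0.794). Interferon response had a median of -0.01 without control library 1 (adjusted p = 0.888) and -0.13 without knockdown library 1 (0.697). By fry's test for change in either direction, 5 lists passed, namely contractile genes (adjusted p = 0.0415), matrix (0.0394), p53 targets (0.0133), the respiratory chain (0.00917) and RNA modification enzymes (0.0133).

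Markers of endothelial cells, leukocytes, adipocytes and mesothelium were low in both groups on the median, unlike those of fibroblasts. The median level of endothelial markers was 0.0642 FPKM in controls and 0.136 FPKM after knockdown, with Eng highest at 57.9 and 75.1 FPKM. Leukocyte markers had medians of 0.0119 and 0.0348 FPKM, with Cd74 highest at 7.75 and 7.98 FPKM, and adipocyte and mesothelial markers 0.101 and 0.107 FPKM, with Msln highest at 4.74 and 4.65 FPKM. Each of these lists had 4 members above the expression filter, too few to test. Schwann and neural markers had medians of 1.12 and 0.733 FPKM, with Ncam1 highest at 100.5 and 85.3 FPKM. Fibroblast markers had medians of 21.0 and 9.25 FPKM and contractile genes 60.1 and 26.4 FPKM. Protein-coding genes held 97.6%, 97.47% and 97.6% of the fragments in controls and 96.2%, 94.6% and 96.5% in knockdown libraries (exact permutation p = 0.1, the smallest possible), so the make-up of the RNA went with the groups. The first principal component, 40.8% of the variance, placed knockdown library 2 at -70.0 and knockdown library 3, at 25.2, beside control libraries 2 and 3 at 30.9 and 29.5, while control library 1 lay at -10.3 and knockdown library 1 at -5.24. Control libraries 2 and 3 were the most alike pair, with a median chi-square per gene of 0.760 against 3.64 to 12.3 in the other 14 pairs. This exceeded the 0.455 of sampling alone, as 2 preparations of the same culture would too, so the values do not show separate cultures. They were fitted as separate samples, and with the pair averaged limma also called 0 genes (346 higher and 477 lower at an unadjusted p under 0.05).

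The ac4C comparison asked which transcripts lost the modification when Nat10 was lowered. The control libraries listed 29998, 29593 and 3479 peaks and the knockdown libraries 3111, 2658 and 2592. The geometric mean was 5.24-fold higher in controls (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). In control libraries 1 and 2, 26881 and 27673 peaks carried 1 identical p-value each, 0.045 and 0.046. Of these, 51.1% and 51.5% lay in genes listed at 0 FPKM in the input library of the same group and number, against 1.09% and 1.198% of the other peaks. Without them the lists held 3117 and 1920 peaks and the fold was 0.990 (exact permutation p = 1).

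**Figure D3:**
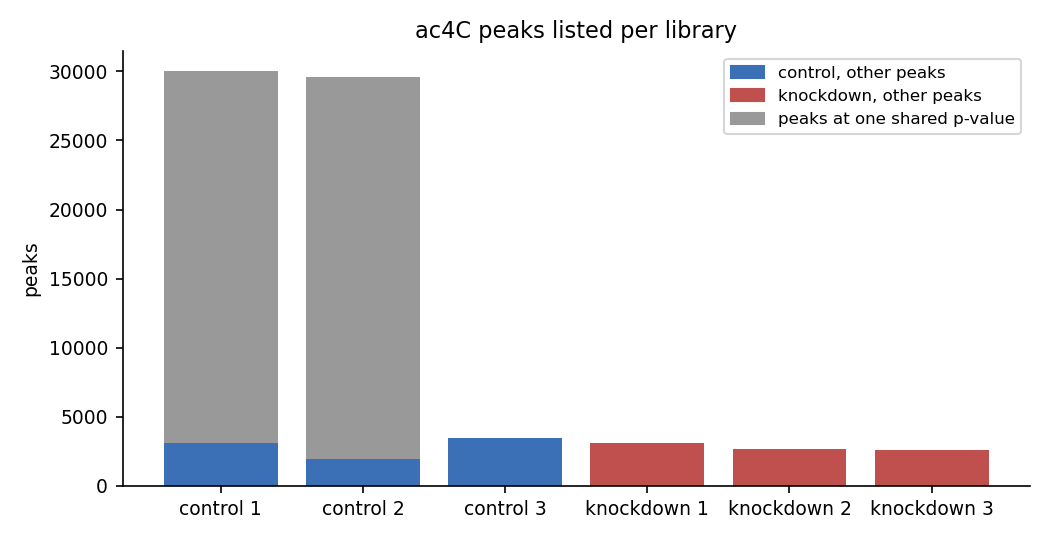
Number of ac4C peaks listed in each control (blue) and Nat10 knockdown (red) library, with peaks at the shared p-value of control libraries 1 and 2 in grey. Without the grey peaks these libraries held 3117 and 1920 peaks, beside 2592 to 3479 in the other 4.

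A peak in all 3 controls and in no knockdown library was found for 303 genes, and the opposite for 27. Without the peaks at a shared p-value these numbers were 67 and 40, and with equal numbers of the remaining peaks 44 and 33. Without those peaks the 2 numbers were 163 and 68, 241 and 59, and 176 and 106 when control library 1, 2 or 3 was left out. They turned to 108 and 110, 98 and 166, and 101 and 150 when knockdown library 1, 2 or 3 was left out. The control-only genes with the highest peak scores included Dstn, an actin-depolymerizing factor, with a peak at chromosome 3, 138051091 to 138051268, Sel1l, part of the degradation machinery of the endoplasmic reticulum, at chromosome 6, 115572679 to 115572948, and the phospholipid-binding Anxa1 at chromosome 1, 237893966 to 237894202. Fau, Nedd4 and Spryd7 completed the 6. Anxa1 RNA stood at 198 ± 21.6 FPKM in controls and 56.5 ± 21.1 FPKM after knockdown, and Dstn RNA at 176 ± 46.5 and 120 ± 15.9 FPKM (SD, n = 3 each). Knockdown-only genes were led by Tmem30a, a subunit of lipid flippases (chromosome 8, 87224066 to 87224214), Gfpt1, the first enzyme of hexosamine synthesis (chromosome 4, 118898924 to 118899104), and the chromatin remodeller Smarca4, followed by Arl6ip4, Swi5 and Clip1. The ranks average scores of lists with different scales, and single libraries set some of them. The -log10 p of Tmem30a had a mean of 109 and a lowest library of 1.82, and that of Spryd7 a highest library of 216 and a lowest of 1.92.

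Peak lists of the same group were about as alike as lists of different groups. Without the shared p-value peaks, genes with a peak overlapped by a mean Jaccard index of 26.4% in the 6 pairs within a group and 24.98% in the 9 pairs between groups. Of 10513 merged regions, 7477 came from 1 library only and 213, in 207 genes, from all 6. Col1a2 carried ac4C peaks in every library, 4, 4 and 5 in controls and 2, 2 and 3 after knockdown, with the best control library 1 peak at chromosome 4, 31567621 to 31569151. Itgb1 carried peaks in control libraries 1 and 3 and in knockdown libraries 2 and 3, so that its peaks did not follow the groups. The count of control-only genes rested on single libraries. It was 455 without control library 2. Without control library 3 it was 19852 and the fold of peaks was 10.7, both set by the shared p-value peaks of control libraries 1 and 2.

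Transcripts bound by NAT10 were longer and more abundant than expressed genes in general. The 3 RIP libraries listed 2268, 1993 and 1773 peaks in 586, 563 and 548 genes, and 362 genes had a peak in all 3. Median enrichments were 1.09, 1.07 and 1.09 on the log2 scale, as the authors gave them. The most enriched symbols were Mycbp2, a ubiquitin ligase (log2 2.32 ± 0.20, SD, n = 3, chromosome 15, 93786460 to 93789174), the growth kinase Mtor (2.31 ± 0.33, chromosome 5, 165364524 to 165364573) and Tenm3 (2.18 ± 0.17), after the unnamed genes AC141959.1, AABR07000398.1 and AABR07062512.1 at 2.82 ± 0.41, 2.56 ± 0.33 and 2.42 ± 0.41. The largest numbers of peaks, picked out after the values were seen, were a mean of 42.7 per library in the cytoskeletal linker Dst, 32.3 in Macf1, another such linker, 30.3 in Ubr4 and 24.3 in Birc6. Bound genes had a median length of 5550 nt and a median level of 37.3 FPKM, against 2054 nt and 10.01 FPKM for all expressed genes. Itgb1 was bound in all 3 libraries, with a peak at chromosome 19, 61702410 to 61705232, in RIP libraries 1 and 2 (log2 0.88 and 0.89). Col1a2 had a peak in 1 RIP library, and Nat10 in none.

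Among the 20 lists, bound genes were over-represented in 5 by Fisher's exact test. They included 11 of 33 matrix genes (adjusted p = 1.02e-08), with Fn1, Fbn1, Tnc and Col4a2, and 9 of 25 integrin and focal adhesion genes (adjusted p = 9.15e-08), with Itgb1, Flna, Tln1 and Vcl. The others were ribosome biogenesis with 5 of 32 (adjusted p = 0.01001), unfolded protein stress with 4 of 25 (adjusted p = 0.0207) and immediate early and heat shock genes with 3 of 18 (adjusted p = 0.0464). Against sets matched on expression and gene length, 0 of the 20 lists passed.

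The next comparison asked if NAT10-bound transcripts were those with ac4C peaks. Of 361 expressed bound genes, 79 carried an ac4C peak in all 3 controls, where 26.6 were given by chance (odds ratio 3.74, Fisher's exact p = 5.02e-19). Sets matched on expression held a mean of 40.2 such genes (95% range 29 to 52, permutation p = 0.0002, the smallest that the random sets can give). Sets matched on expression and length held 68.4 (56 to 81, permutation p = 0.123), and without the shared p-value peaks 59 genes were found against 56.4 in such sets (45 to 68, permutation p = 0.709). Without ac4C control library 3 the odds ratio was 1.16 (Fisher's exact p = 0.216), and for peaks in at least 2 libraries it was 1.65 (Fisher's exact p = 3.14e-08). Both are void as checks, since the shared p-value peaks filled these sets. Control libraries 1 and 2 both listed a peak in 21533 genes, and in 837 without the shared p-value peaks.

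**Figure D4:**
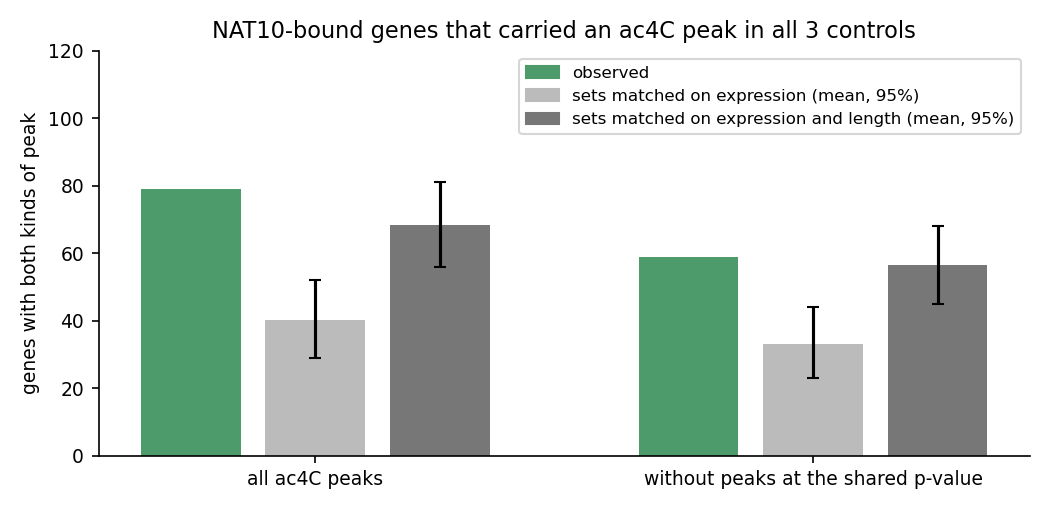
Number of NAT10-bound genes with an ac4C peak in all 3 controls (green), beside the mean and 95% range of 10000 random gene sets matched on expression or on expression and length (grey). The observed 79 and 59 genes lay above the sets matched on expression and within the ranges of those matched on both.

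Transcripts with ac4C peaks or bound by NAT10 stood slightly lower after knockdown, but the ac4C genes did not pass. The call for bound genes was lost with an estimated correlation (p = 0.598) and pointed up without knockdown library 2. The 991 expressed ac4C genes had a median log2 change of -0.07 against -0.01 for the rest (camera p = 0.127, p = 0.276 with an estimated correlation). Without the shared p-value peaks, 577 ac4C genes had a median of -0.11 (camera p = 0.00955, p = 0.216 with an estimated correlation). They included the contractile genes Acta2, Mylk and Lmod1 and the collagen genes Col1a1, Col1a2 and Col3a1, and 5 of 20 lists were over-represented among them. These were matrix with 10 of 33 (Fisher's exact test, adjusted p = 1.48e-05), contractile genes with 5 of 18 (0.00384), ribosomal proteins with 8 of 43 (0.00357), unfolded protein stress with 6 of 25 (0.00357) and growth factors with 5 of 26 (0.0178), and 0 lists passed against matched sets. The 361 bound genes had a median of -0.10 (camera p = 0.0170, p = 0.598 with an estimated correlation), and those of the better-scoring part of each list -0.17. No gene passed as lower by limma, so Fisher's test of such genes could not be computed. The medians lay below those of sets matched on expression for ac4C genes (permutation p = 0.0202) and for bound genes (permutation p = 0.0316). With sets matched on expression and length the values were 0.0004 and 0.0126 (permutation p). Such random sets treat genes as independent, whereas camera estimated correlations of 0.0152 among ac4C genes and 0.221 among bound genes. Without knockdown library 2 the median of bound genes was -0.02, with a test pointing up and a camera p of 0.734, and without knockdown library 3 it was -0.24. The camera p of bound genes was 0.0650 without knockdown library 1, 0.0540 without RIP library 1 and 0.09998 for peaks in at least 2 libraries. Without ac4C control library 3 the median of ac4C genes was 0.02 with a camera p of 0.326, and it was 0.0048 for peaks in at least 2 libraries. Both of these sets were filled by the shared p-value peaks, so they do not check the lower median.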

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

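All tests in this part were chosen only after the result was seen, and none was planned.

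Small nucleolar RNA genes, a class the comparisons above leave aside, took a larger part of the fragments in knockdown libraries, 0.320% ± 0.0223 against 0.198% ± 0.00866 in controls (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Of 376 such genes, 286 had a positive log2 change, with a median of 0.46 (camera adjusted p = 5.08e-11, but adjusted p = 0.0829 with an estimated correlation, which does not pass). RF00377 (ENSRNOG00000057709), picked out after its values were seen, stood at 3.84 ± 0.787 and 13.8 ± 2.39 FPKM. Small nuclear RNA genes had a median of 0.30 and 5S and other ribosomal RNA genes 0.51 (adjusted p = 0.0969 and adjusted p = 0.0829 with an estimated correlation, neither passing). These genes are thinly covered, with a median of 5.5 fragments per small nucleolar RNA gene.

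The tables argue against gene length alone as the cause. The equally short microRNA genes had a median of -0.0346, although on a median of 2.67 fragments per gene. Protein-coding genes of up to 300 nt had a median of -0.0292. Other short classes lay higher, with 0.15 for small Cajal body RNA genes and 0.13 for mitochondrial transfer RNA genes, beside the small nuclear and ribosomal RNA genes above. The median of small nucleolar RNA genes was at least 0.49 under quantile normalization and scaling to the total. Scaling to the total is no test of the authors' scaling, because 1 factor per library shifts all classes about alike. It gave medians of 0.59 for small nucleolar RNA genes and 0.11 for protein-coding genes, against 0.46 and -0.03 in the main fit. A larger share of nuclear or unspliced RNA in the knockdown libraries may account for the pattern and cannot be told apart from a change in these RNAs, because gene values hold no intron reads and the median of 0.0147 in long intergenic RNA genes decides nothing. The 10 splits of the 6 libraries are too few for a share under 0.05 (1 split as large, the real one), with a real median of 0.46 and a highest other of 0.27. An effect of Nat10 loss, whose protein works in the nucleolus, remains a hypothesis.

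The long ac4C peak lists of control libraries 1 and 2 were weighed as a second pattern. Of the peaks at the shared p-value, at least 51.1% lay in genes listed at 0 FPKM, which is consistent with peaks having been listed regardless of signal. A loss of ac4C after knockdown is argued against for the shared p-value peaks, at least 37.3%, in genes at 0 FPKM in all 6 input libraries, which held no measured RNA (0.513% and 0.365% of the other peaks of these lists). For the shared p-value peaks in genes with RNA, at least 61.7% of them, such a loss and the listing cannot be told apart, because peak lists hold no reads. Some of them in control list 1 spanned the whole gene, since their lengths gave the authors' divisor for 945 to 1204 genes per input library. Rows of whole genes are what a listing regardless of signal would give, but they cover only a part of these peaks. For control-only genes the 10 splits of the 6 ac4C libraries are too few for a share under 0.05 (1 split as large, the real one), with 303 genes in the real split and 298 in the highest other, and without the shared p-value peaks 67 and 82.

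For the lower contractile and matrix genes, length and expression level are argued against, since 0 of 10000 sets of genes matched on both had a median as low for either list. A single knockdown library is argued against as well, since the middle one deviated by -1.24 for contractile and -0.86 for matrix genes (lowest control -0.16 and -0.08), although knockdown library 3 stood at -0.10 for matrix genes. The fibroblast markers did not rise, with a median of -0.55 that lay below every control in all 3 knockdown libraries. They do not decide on a shift from smooth muscle cells to adventitial fibroblasts, because some of them are matrix genes themselves. Col14a1 is a collagen gene and Dcn is in both lists, so a fall of matrix genes could lower them in any mix of cells. The 10 splits are too few for a share under 0.05 (1 split as large for either list, the real one), with medians of -1.26 and -0.83 in the real split and sizes of 0.87 and 0.78 in the highest other. Loss of Nat10, any other effect of the hairpin virus and RNA quality cannot be told apart, because the series has 1 knockdown virus and the protein-coding share of fragments lay lower in every knockdown library (at most 96.5%) than in any control (at least 97.47%).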

How the results depend on the processing

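Quality weights, voom, scaling to the total, removal of shared p-value peaks, length matching and the other additions named in the processing were chosen only after the results were seen; the rest were planned. The replicate block changed no gene call (0 genes, lowest adjusted p 0.442) and gave 9 lists; same-numbered libraries did not deviate together (correlations -0.21, -0.28 and 0.18), and not every library correlated best with its own number (0.41 for control library 1 with knockdown library 2).

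Of 663 comparisons over 37 named genes, 636 gave the same call and 27, all with quality weights, passed the threshold; none reversed. Of 126 comparisons over the 7 called lists, 113 gave the same call, 12 fell below the threshold and 1 reversed (cell cycle, -0.11 without knockdown library 1, up to 0.42 without knockdown library 3). At the preset correlation the contractile, matrix and fibroblast lists and the small nucleolar RNA genes passed in all 18 alternatives. With an estimated correlation none did (adjusted p = 0.0829 for small nucleolar RNA genes). Limma without the trend leaves camera unchanged by construction, and median-of-ratios scaling nearly repeats the deposited scaling. Both are counted among these alternatives and the 126 comparisons, where they check little.

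Quality weights, which were largest for control libraries 2 and 3, gave a Nat10 log2 of -0.97, 120 genes higher and 215 lower. The highest other split gave 256 genes. Leaving out 1 library gave 0 to 1 genes higher (Zfand2a without knockdown library 2; 30.9 and 139 FPKM over all libraries) and 0 to 1 lower (RF00494 without control library 3; 54.6 and 2.19 FPKM over all libraries). An estimated correlation gave 0 lists and fry's directional test 0. The cause was not tested for these changes or for those that follow.

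For ac4C peaks the better-scoring part is void as a check, since ties at the shared p-value kept control lists 1 and 2 whole while the other lists were halved by p. The fold of ac4C peaks was 8.28 there, 0.990 without shared p-value peaks and 3.65 to 10.7 without 1 library; with equal numbers it is equal by construction. Control-only genes numbered 171 there (12 knockdown-only), 54 with equal numbers (46 knockdown-only), 67 without shared p-value peaks, 44 with equal numbers of the rest, 20134 for peaks in at least 2 libraries (236 knockdown-only; 446 without shared p-value peaks, against 346 knockdown-only) and 371 to 19852 without 1 library; control-only regions numbered 140 (1 base) and 55 (50% overlap), or 58 and 48 without shared p-value peaks, against 42 and 40 knockdown-only in both cases.

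The ac4C genes' median was -0.11 in that part, which control list 3 alone narrowed, -0.14 with equal numbers, -0.11 without shared p-value peaks, -0.15 with equal numbers of the rest, 0.0048 for peaks in at least 2 libraries and -0.0970 to 0.0187 without 1 library. The 0.0048 and the 0.0187, without ac4C control library 3, rest on sets filled by shared p-value peaks. The bound genes' median was -0.17 in the better-scoring part, -0.0787 for at least 2 libraries, -0.10 with an estimated correlation (p = 0.598) and -0.243 to -0.0245 without 1 library. The odds ratio of bound and ac4C genes was 1.16 to 4.37 without 1 library, 1.65 for at least 2 libraries and 5.43 in the better-scoring part (void in the same way). The 1.16, without ac4C control library 3, and the 1.65 rest on sets filled by shared p-value peaks. The matched ratio was 1.15, or 1.05 without shared p-value peaks. Fisher's test of fallen genes gave no value. Depth limits small RNAs most. With 3 libraries per group, 15% of simulated 2-fold and 86% of 4-fold changes were recovered (58% and 93% at the spread of controls). Every simulated gene had the same dispersion, so these shares may not hold for the real data. There limma called 0 genes, although Col4a2 and Col5a2 differed 6.71-fold and 6.81-fold on the fitted scale.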

Other observations

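All tests in this part were chosen only after the results were seen.

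Beyond the genes named by rule, several abundant genes of the contractile and matrix programmes stood lower after Nat10 knockdown, picked out here after their values were seen. Acta2, smooth muscle actin, stood at 1714 ± 401 FPKM in controls and 483 ± 424 FPKM after knockdown (SD, n = 3 each), and Myh11, smooth muscle myosin, at 24.1 ± 20.3 and 5.92 ± 0.440 FPKM. Col3a1 stood at 1706 ± 58.2 and 285 ± 258 FPKM, while Col1a1, the partner chain of Col1a2, stood at 6081 ± 186 and 4485 ± 1720 FPKM. The matricellular growth factors Ccn2 and Ccn1 stood at 3892 ± 415 and 1274 ± 159 FPKM in controls and at 1464 ± 1244 and 660 ± 421 FPKM after knockdown. Each had an adjusted p over 0.05 in limma.

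The following stress genes were also picked out after their values were seen, and each had an adjusted p over 0.05 in limma. Hsph1, a heat shock chaperone, stood at 56.9 ± 5.79 FPKM in controls and 187 ± 94.7 FPKM after knockdown, and Jun at 22.7 ± 2.24 and 47.1 ± 21.2 FPKM, while Egr1 stood at 226 ± 129 and 77.3 ± 85.2 FPKM and Fos at 27.4 ± 12.1 and 10.8 ± 6.80 FPKM. The cell cycle inhibitor Cdkn1a stood at 129 ± 34.5 and 280 ± 136 FPKM, and Mdm2, the negative regulator of p53, at 84.1 ± 21.3 and 138 ± 50.6 FPKM, opposite in direction to the p53 target Ccng1.

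Genes with an ac4C peak in 1 group only, without shared p-value peaks, had a median log2 expression change of -0.08 when the peak was in controls (66 genes, 42 of them lower) and 0.07 when it was in knockdown libraries (40 genes, 23 of them higher). Peaks are easier to call in abundant transcripts, so choosing genes by their peaks can give such medians by itself. The medians therefore do not show an effect of ac4C on RNA level. A candidate explanation for the overlap of NAT10-bound and ac4C genes is that long and abundant transcripts more readily give both kinds of peak, since the overlap was 1.05 times that of sets matched on expression and length.

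For the following results the 10 splits of the 6 input libraries are too few for a share under 0.05. The real split called 0 genes and the highest other 18 (10 of 10 splits as large). That other split set control library 1 and knockdown libraries 1 and 2 against the rest, with 1755 genes at an unadjusted p under 0.05 against 1679, which points to a structure of the samples besides the groups. With quality weights the real split called 335 genes and the highest other 256 (1 split as large). For lists the real split called 7 and the highest other 10 (7 splits as large). For ac4C genes the real camera p was 0.127 and the lowest other 0.0491 (4 splits as small), and for bound genes 0.0170 and 3.29e-09 (7 splits as small).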
